A study of Arabidopsis thaliana with 12 samples.

How the data were processed

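RNA of whole Arabidopsis thaliana seedlings was sequenced on an Illumina HiSeq instrument, per the labels and the design text. Seedlings were 10 days old and either wild type (WT) or cry1, a mutant of the blue light receptor cryptochrome 1. They had grown in the dark and were collected either in the dark or after 1 h of blue light at 40 µmol m-2 s-1. Total RNA was isolated with RNAiso Plus and libraries were made with a TruSeq RNA kit, per the labels' protocols. Each of the 4 groups has 3 libraries, 12 in all. The labels do not say whether the 3 libraries of a group came from separate sowings, so p-values measure the spread between these libraries, which may be partly technical.

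The deposited values are TPM, transcript abundances scaled to the library's total, 1 table per library with 32833 genes. This unit was read from the values, which sum to between 980965 and 996431 per library. The submitters' processing notes name the genome build TAIR10 and the programs Trimmomatic 0.36, HISAT2, TopHat, Bowtie2, Cufflinks and DESeq 1.18.0, with no roles or order. The annotation release, the strand setting and the handling of reads shared between genes are not given in the sources used here. TPM carries no read depth, so no counting interval or detection limit can be given, and a value of 0 is described only as listed at 0. TPM is also relative: a large rise of some RNAs lowers the values of all others in that library.

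Gene identifiers were matched to the RefSeq annotation of the assembly TAIR10.1. Of the 32833 identifiers, 32548 matched, and the rest are the 133 genes of the plastid genome and 152 of the mitochondrial genome, which were kept under the identifiers of the files. Symbols come from the gene lists described next or else from that annotation. A gene with no symbol there is named by its identifier.

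Fold changes were computed from the TPM values as deposited, as log2(TPM + 1), for the 20314 genes with a TPM of at least 1 in at least 3 libraries. The pseudocount of 1 understates changes of genes with low TPM. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with a trend of the variance on the mean and no block. The threshold was a Benjamini-Hochberg adjusted p under 0.05 within each contrast. The design written beforehand named this test for normalized values and another for counts, which TPM does not allow. There were 5 contrasts: the light response in WT, the light response in cry1, the genotypes in blue light, the genotypes in the dark, and the interaction, which is the cry1 light response minus the WT light response.

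Before the data were examined, 21 gene lists with 326 members were fixed, and 310 of their symbols match the annotation. They are photoreceptors, light signalling, PIF and related bHLH, flavonoid biosynthesis, light-harvesting antenna, chlorophyll biosynthesis, photoprotection, carbon fixation, circadian clock, auxin response, brassinosteroid, gibberellin, cell wall loosening, touch wound and early stress, heat shock, abscisic acid and cold, dark and sugar starvation, reactive oxygen scavenging, root markers, seed storage and oil body, and housekeeping. Root markers, seed storage and oil body, and housekeeping were chosen as signs of sample makeup. The plastid and mitochondrial genomes made 2 more lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 23 lists of a contrast. Calls of lists are those of camera, and fry values are given only where fry is named. Members past the threshold were counted over all genes and adjusted over the list alone.

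Named genes follow a rule fixed at the same time. For each contrast it takes the 8 genes with the largest log2 fold change in each direction among those past the threshold, with a mean of at least 5 TPM in the higher group. Except for the interaction, the 3 values of one group must also lie above the 3 of the other. It adds up to 4 members of each list with the smallest adjusted p, and CRY1 and CRY2. Any other gene named is said to have been chosen after its values were seen.

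The fit was tested on simulated data made from the real means and spreads, with 200 genes changed by 1 or 2 on the log2 scale. For WT blue versus WT dark, 34 of 100 genes changed by 1 and 88 of 100 changed by 2 were recovered among 20019 genes, with 4 false calls. For the interaction, 13 of 100 and 75 of 100 were recovered among 20028 genes, with 7 false calls. A change of 1 was therefore often missed in these simulations. They drew each gene independently around 1 mean, with no difference in scaling between libraries. Far fewer genes were changed than were called in the data. The recovery and the false calls may therefore differ in the real data.

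Alternatives were a TMM-type scaling of the TPM values (trimmed mean of log ratios, without weights), quantile normalization, 2 other filters, a pseudocount of 0.1, limma without the trend, an added log2 fold change of at least 1, only the 6 libraries compared, the replicate number as a block, organelle genes left out, and each library left out in turn. A fit on nuclear protein-coding genes only, and counts of the starvation, touch and low oxygen lists with each library left out, were chosen after seeing the data. No 2 libraries held the same values: between any pair, at least 98.9% of the tested genes differed.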

Results

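The series asked how dark-grown Arabidopsis seedlings with and without the blue light receptor cryptochrome 1 change their RNA levels in the first hour of blue light. WT and cry1 seedlings were compared in the dark and after 1 h of blue light, with 3 libraries in each of the 4 groups. Between 18409 and 19380 genes had a TPM of at least 1 in a library. Read depth is not known from TPM values. Log2 values correlated across the tested genes at r = 0.955 to 0.977 within groups and at 0.822 to 0.956 between groups. Values are given as mean TPM ± SD (n = 3 libraries per group), and log2 fold changes with their SE, from limma on log2(TPM + 1) with Benjamini-Hochberg adjusted p. Members of near-identical families (SAUR19 to SAUR24, the LHCB1, LHCB2 and RBCS genes, small heat shock proteins) may share reads, so the value of a single member is uncertain.

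CRY1 (AT4G08920, chromosome 4, 5723651 to 5727268 in TAIR10.1) encodes cryptochrome 1, and its RNA checks the genotype labels. It stood at 58.6 ± 1.98 TPM in WT dark and 35.6 ± 13.3 in WT blue, against 0.98 ± 0.70 in cry1 dark and 0.58 ± 0.56 in cry1 blue. All 6 WT libraries lay above all 6 cry1 libraries. CRY2 (AT1G04400), its closest relative, was at 94.2 ± 6.14 TPM in WT dark, 45.7 ± 7.73 in WT blue, 59.7 ± 10.8 in cry1 dark and 51.8 ± 7.36 in cry1 blue. CRY2 fell with light in WT (log2 fold change -1.04, adjusted p = 0.00101). Its value in cry1 dark was below WT dark (-0.67, adjusted p = 0.0171), a call lost with TMM-type scaling (adjusted p = 0.0599) and without WT dark replicate 1 or cry1 dark replicate 2.

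**Figure D1:**
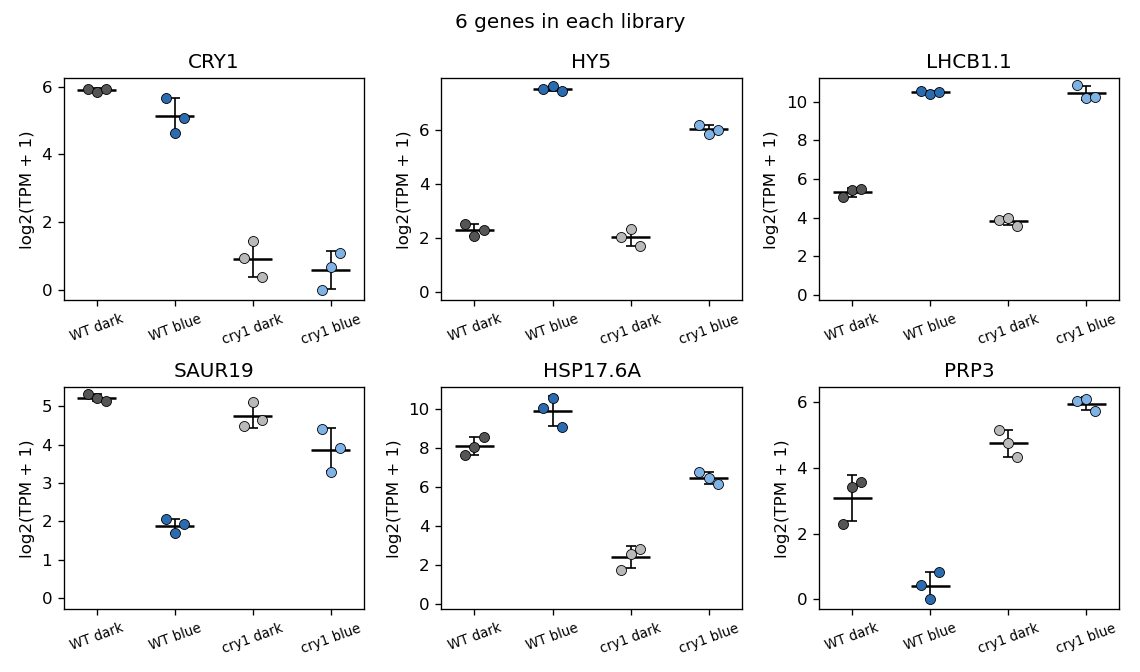
The log2(TPM + 1) of 6 genes in each of the 12 libraries, with points for libraries, horizontal lines for group means and error bars for SD (n = 3). CRY1 is near 0 in cry1, HY5 and LHCB1.1 are higher in blue light in both genotypes, SAUR19 is lowest in WT blue, HSP17.6A is lower in cry1 in both conditions, and PRP3 is higher in cry1.

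After 1 h of blue light, 15 of 26 light signalling, 13 of 18 antenna and 8 of 12 photoprotection genes were higher in WT, and 18 of 30 auxin response genes were lower. HY5, the transcription factor that promotes seedling greening, rose from 4.02 ± 0.79 to 185.5 ± 10.8 TPM (log2 fold change 5.23 ± 0.19 SE, adjusted p = 4.58e-09). LHCB1.1, an antenna protein of photosystem II, rose from 38.8 ± 5.74 to 1446 ± 94.5 TPM, and ELIP1, a stress-inducible relative of the antenna proteins, from 0.76 ± 0.33 to 87.9 ± 44.7. XTH15, an enzyme that remodels cell wall xyloglucan, fell from 837.5 ± 23.1 to 48.0 ± 14.2 TPM, and the auxin response gene IAA29 from 46.1 ± 3.61 to 2.51 ± 0.48. In all, 1976 of 20314 genes were higher and 5144 were lower in WT blue.

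Of 26 light signalling genes, 15 were higher and 5 lower in WT blue (16 and 5 adjusted over the list alone), among them SIG5 (4.28), BBX30 (4.28) and BBX31 (2.87 on the log2 scale). Of 18 antenna genes 13 were higher and 0 lower (13 adjusted over the list alone), of 12 photoprotection genes 8 higher and 1 lower, of 10 carbon fixation genes 7 higher and 0 lower, and of 20 chlorophyll biosynthesis genes 11 higher and 1 lower. NPQ4, the protein PsbS, rose by a log2 fold change of 3.70, RBCS1B by 3.63, and GUN4, an activator of chlorophyll synthesis, went from 11.7 ± 0.87 to 152.8 ± 66.4 TPM. Of 16 flavonoid biosynthesis genes 12 were higher, with F3H at 3.56 and UGT78D2 from 9.61 ± 1.0 to 91.7 ± 23.2 TPM. Of 12 heat shock genes 10 were higher, with HSP70 from 343 ± 73.2 to 2257 ± 239 TPM. Each of these lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.327 for chlorophyll biosynthesis, 0.134 for carbon fixation and 0.0896 for the other 5, so none passed.

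Of 30 auxin response genes 18 were lower and 0 higher in WT blue (19 lower adjusted over the list alone), including SAUR19 from 36.4 ± 2.27 to 2.71 ± 0.47 TPM. Of 16 cell wall loosening genes 10 were lower and 1 higher, with the expansin EXPA8 from 114.5 ± 12.1 to 14.3 ± 5.88 TPM, and of 11 brassinosteroid genes 7 were lower, with the biosynthesis gene CPD from 354 ± 29.3 to 80.9 ± 12.4. Of 10 dark and sugar starvation genes 7 were lower and 1 higher, with DIN6, an asparagine synthetase, from 291.5 ± 111 to 22.3 ± 13.1 TPM. These 4 lists also passed camera, and lost the call with an estimated correlation (adjusted p = 0.0896, 0.261, 0.471 and 0.529). PHYA, phytochrome A, fell from 329 ± 15.8 to 57.5 ± 20.3 TPM among 14 photoreceptors, of which 6 were lower and 2 higher. Of 16 PIF and related bHLH genes 9 were lower and 3 higher, with PRE6 at -3.19, and of 16 gibberellin genes 9 were lower and 1 higher, with GAI at -2.09. These 3 lists did not pass camera (adjusted p = 0.103, 0.0675 and 0.15). Of 19 circadian clock genes 6 were higher and 4 lower, and of 10 abscisic acid and cold genes 5 were higher and 1 lower. Both passed camera, but not with an estimated correlation (adjusted p = 0.425 and 0.0896). Of 19 touch wound and early stress genes 3 were higher and 2 lower, of 8 reactive oxygen scavenging genes 3 higher and 1 lower, of 10 root markers 3 lower, and of 10 housekeeping genes 3 lower as deposited, but 1 higher and 2 lower with TMM-type scaling. The touch list passed camera (adjusted p = 0.0328) and lost the call with an estimated correlation (adjusted p = 0.631). The reactive oxygen scavenging, root marker and housekeeping lists did not pass camera (adjusted p = 0.119, 0.0917 and 0.553). With TMM-type scaling 1 brassinosteroid gene and 2 gibberellin genes were higher, and 1 touch and 0 abscisic acid and cold genes were lower. None of the 2 measured seed storage and oil body genes was called. Adjusted over the list alone, the counts were 13 higher for flavonoid biosynthesis, 8 for carbon fixation, 11 for heat shock and 9 for the circadian clock, and for the other lists of nuclear genes not given above they equalled those over all genes.

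Among the largest changes in WT blue were the rises of AT3G56290 (6.43) and cPT4 (4.99), and the falls of AT3G10040 (-5.82), AT2G17850 (-5.41), AT1G33055 (-5.34) and NIP2;1 (-4.96). The non-coding RNA AT2G08665 was listed at 0 in the 3 WT dark libraries and at 858, 615 and 1765 TPM in WT blue, but its values varied widely within cry1, with 4469, 0 and 0.15 TPM in cry1 blue and 79.2, 0 and 0 in cry1 dark. The median log2 fold change of all genes was -0.27 as deposited. TMM-type scaling shifted it by 0.27 and gave 3561 higher and 3384 lower genes, so the higher share of calls was 27.8% as deposited and 51.3% with that scaling. The same 1974 genes were higher and 3384 lower under both. Without WT dark replicate 1, WT dark replicate 2 or WT blue replicate 2, 3299, 3077 or 3025 genes were lower.

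In cry1, 16 of 18 antenna, 10 of 10 carbon fixation and 9 of 12 heat shock genes were higher after blue light, with median log2 fold changes of the lists of 2.37, 2.15 and 2.95. LHCB1.1 rose from 13.2 ± 2.07 to 1426 ± 369 TPM (log2 fold change 6.63 ± 0.19, adjusted p = 5.69e-10), LHCB2.1 from 23.4 ± 4.04 to 1249 ± 222, and HY5 from 3.15 ± 0.88 to 64.8 ± 7.83. XTH15 fell from 1203 ± 63.2 to 109.6 ± 20.7 TPM. In all, 1867 genes were higher and 1164 lower, and 1824 were lower with quantile normalization. Of 18 antenna genes 16 were higher and 0 lower (17 adjusted over the list alone), of 10 carbon fixation genes 10 higher, of 12 photoprotection genes 8 higher, of 20 chlorophyll biosynthesis genes 13 higher, of 26 light signalling genes 16 higher and 3 lower, and of 12 heat shock genes 9 higher. The antenna and photoprotection lists passed camera with the preset and the estimated correlation (adjusted p = 0.0388 for both). The other 4 passed only with the preset correlation (adjusted p = 0.0572, 0.208, 0.0684 and 0.0875 with an estimated correlation).

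Of 19 circadian clock genes 9 were higher and 1 lower in cry1 blue, with CCA1 from 0.86 ± 0.35 to 26.1 ± 4.28 TPM. Of 10 abscisic acid and cold genes 5 were higher, with COR15A from 0.53 ± 0.34 to 54.9 ± 27.7 TPM, and of 10 root markers 6 were higher, with the iron transporter IRT1 at 1.45. These last 2 lists kept their camera call with an estimated correlation (adjusted p = 0.0388 for both), and the clock list lost it (adjusted p = 0.176). Of 19 touch wound and early stress genes 8 were lower and 0 higher, with CML38 from 65.8 ± 48.5 to 2.49 ± 0.78 TPM, and adjusted over the list alone 13 were lower. In this list the third cry1 dark library stood apart, with a mean log2 value of 5.25 against 4.3 and 3.77 in the other two, and 7 genes were lower without it and 13 without cry1 dark replicate 2. Of 30 auxin response genes 10 were lower and 1 higher, of 10 dark and sugar starvation genes 4 lower, and of 16 flavonoid biosynthesis genes 5 higher. The third cry1 dark library stood apart in the starvation list too, with a mean log2 value of 6.29 against 5.16 and 5.08, and 3 starvation genes were lower without it and 2 without cry1 blue replicate 1. The touch, auxin, starvation and flavonoid lists lost their camera call with an estimated correlation (adjusted p = 0.287, 0.267, 0.374 and 0.274). Photoreceptors (2 higher, 1 lower of 14), PIF and related bHLH (5 and 6 of 16), brassinosteroid (3 and 0 of 11), gibberellin (3 and 2 of 16), cell wall loosening (2 and 4 of 16) and reactive oxygen scavenging (2 and 0 of 8) did not pass camera. No housekeeping or seed storage gene was called. With TMM-type scaling 3 photoreceptors, 1 brassinosteroid gene and 0 circadian clock genes were lower. Adjusted over the list alone, the counts were 14 higher for chlorophyll biosynthesis, 9 for photoprotection, 11 for the circadian clock, 8 for flavonoid biosynthesis, 6 for abscisic acid and cold and 7 for root markers, and 13 lower for auxin response, 5 for light signalling, 3 for photoreceptors, 3 for gibberellin, 2 for brassinosteroid and 1 for reactive oxygen scavenging. AT3G02790, a zinc finger protein, was listed at 24.6, 77.6 and 35.9 TPM in the cry1 dark libraries and at 0 in the other 9. Without cry1 dark replicate 3, cry1 blue replicate 1 or cry1 blue replicate 3, 714, 744 or 632 genes were lower in cry1 blue.

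Across the tested genes, the light responses of WT and cry1 correlated at Pearson r = 0.497 and Spearman rho = 0.368. They share no libraries, and genes are not independent replicates. Called in both were 971 genes higher in both, against 181.6 for independent lists of these sizes, and 582 lower in both, against 294.8. A further 150 genes were called in opposite directions. Over genes called in WT, the regression slope of the cry1 change on the WT change was 0.532. Over genes called in cry1, the slope of the WT change on the cry1 change was 0.608. How far noise in the fold changes and the choice of genes affect these slopes was not tested.

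**Figure D2:**
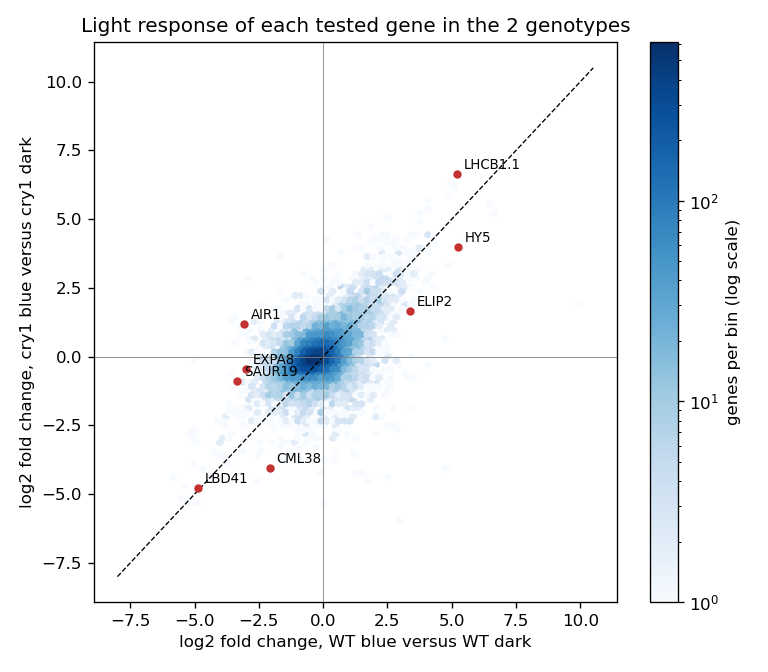
Log2 fold change in blue light against dark for each of the 20314 tested genes, in WT (x axis) and in cry1 (y axis). Colour gives genes per bin on a log scale and the dashed line marks equal change. HY5 and ELIP2 lie below the line, EXPA8 and SAUR19 lie above the line, at -2.99 and -3.34 in WT and at -0.47 and -0.88 in cry1, and LBD41 fell in both genotypes.

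In blue light, 16 of 19 touch wound and early stress genes and 11 of 12 heat shock genes were lower in cry1 than in WT, and 7 of 10 root markers, 13 of 30 auxin response genes and 57 of 74 genes of the plastid genome were higher. PER4, a peroxidase, was at 366 ± 279 TPM in WT blue and 0.78 ± 0.28 in cry1 blue (log2 fold change -7.35 ± 1.02, adjusted p = 0.000309). CYP71A12, an enzyme of camalexin synthesis, was at 207 ± 95.3 against 2.36 ± 0.32 TPM. PRP3, a cell wall protein of root hairs, was at 0.36, 0 and 0.77 TPM in the WT libraries and 64.4, 66.4 and 52.2 in cry1 (5.52 ± 0.33). HY5 was lower in cry1 blue by a log2 fold change of -1.51 (adjusted p = 0.000174). In all, 2213 genes were higher and 2906 lower in cry1 blue.

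Of 19 touch wound and early stress genes 16 were lower and 0 higher in cry1 blue (18 lower adjusted over the list alone), with ZAT12 at 195.7 ± 123 TPM in WT and 6.16 ± 1.96 in cry1, and WRKY40 at 112 ± 48.9 and 5.55 ± 2.32. Of 12 heat shock genes 11 were lower, with HSP17.6B at 748 ± 357 and 64.9 ± 7.16 TPM. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.278 and 0.229). Of 10 root markers 7 were higher and 0 lower, including the root hair expansins EXPA18 (3.86) and EXPA7 (3.78) and COBL9 (0.16 ± 0.0802 TPM in WT and 3.61 ± 0.0635 in cry1), and this list passed camera with an estimated correlation too (adjusted p = 0.0462). Root markers were listed as a sign of sample makeup. Whether the libraries differed in their share of root tissue was not tested, here or in the other contrasts. Among the largest rises outside the lists were RHS13 (5.01), AGP3 (5.20) and HRGP1 (5.26). Of 30 auxin response genes 13 were higher and 3 lower, with SAUR19 at 2.71 ± 0.47 TPM in WT and 14.4 ± 5.84 in cry1, and of 16 cell wall loosening genes 9 were higher and 3 lower, with EXPA8 at 14.3 ± 5.88 and 57.0 ± 15.2. Both lists lost the call with an estimated correlation (adjusted p = 0.278 for each).

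Of 26 light signalling genes 9 were lower and 1 higher in cry1 blue, with BBX30 at -1.46 and RUP1 at -1.57, and of 16 flavonoid biosynthesis genes 6 were lower, with MYB90, a regulator of anthocyanin synthesis, at 8.03 ± 2.74 TPM in WT and 1.38 ± 0.87 in cry1. Of 19 circadian clock genes 9 were lower and 1 higher, and of 10 dark and sugar starvation genes 6 were lower. These 4 lists lost their camera call with an estimated correlation (adjusted p = 0.401, 0.444, 0.401 and 0.401). Of 12 photoprotection genes 2 were lower, ELIP2 (-3.23) and ELIP1 (-1.69). Antenna genes had 3 higher and 1 lower of 18, chlorophyll biosynthesis 2 higher of 20, carbon fixation 0 of 10 and photoreceptors 2 higher and 1 lower of 14. PIF and related bHLH had 4 higher and 5 lower of 16, gibberellin 5 and 1 of 16, brassinosteroid 3 and 0 of 11, abscisic acid and cold 4 and 2 of 10, and reactive oxygen scavenging 1 and 3 of 8. Of these, the brassinosteroid list passed camera (adjusted p = 0.0296) and lost the call with an estimated correlation (adjusted p = 0.512). ACT2 and ACT8, housekeeping actins, were higher in cry1 blue (0.58 and 0.69), the ACT2 call being lost without WT blue replicate 2 or cry1 blue replicate 3. Of 10 housekeeping genes 3 were higher and 1 lower as deposited, and 3 and 0 with TMM-type scaling. That scaling also gave 2 higher carbon fixation genes and 2 lower photoreceptors, and quantile normalization 4 higher chlorophyll biosynthesis and 5 higher brassinosteroid genes. Adjusted over the list alone, the counts were 14 higher and 4 lower for auxin response, 10 lower for the circadian clock, 7 lower for starvation, 5 higher for abscisic acid and cold, 2 higher for reactive oxygen scavenging, 1 higher for chlorophyll biosynthesis, 64 higher for the plastid and 30 for the mitochondrial genome, and otherwise as over all genes.

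Of calls in blue light, 43.2% were higher as deposited and 53.8% with quantile normalization (3641 higher and 3122 lower), and TMM-type scaling gave 3322 higher. Without WT blue replicate 2 or cry1 blue replicate 3, 1231 or 1423 genes were higher, and without cry1 blue replicate 3, 1928 were lower.

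**Figure D3:**
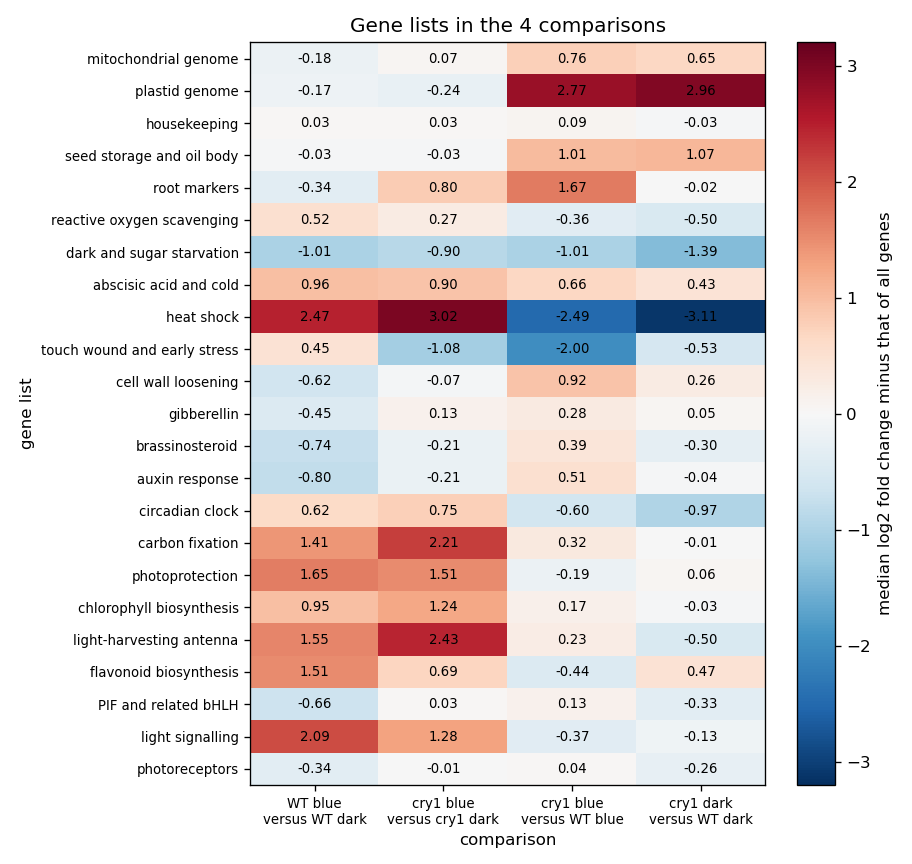
Median log2 fold change of each gene list minus the median of all tested genes, for 4 comparisons (columns), from the values as deposited. Heat shock genes lie at 2.47 and 3.02 in the light responses and at -2.49 and -3.11 in cry1 against WT in blue light and dark, and the plastid genome at 2.77 and 2.96 in cry1 against WT.

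In the dark, 12 of 12 heat shock, 15 of 19 circadian clock and 8 of 10 starvation genes were lower in cry1 than in WT, and 62 of 74 genes of the plastid genome were higher. HSP17.6A was at 280 ± 93.1 TPM in WT dark and 4.43 ± 1.9 in cry1 dark (log2 fold change -5.71 ± 0.37, adjusted p = 2.58e-06). CCA1, a morning regulator of the circadian clock, was at 19.7 ± 10.3 against 0.86 ± 0.35 TPM. DHAR2, a dehydroascorbate reductase, was at 160 ± 19.9 against 3.24 ± 2.93 TPM, and its neighbour AT1G75280 at 77.9 ± 8.83 against 0.89 ± 0.49. In all, 1082 genes were higher and 4767 lower in cry1 dark.

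Of 12 heat shock genes 12 were lower (12 adjusted over the list alone), with HSP90.1 at 229 ± 30.2 TPM in WT and 23.2 ± 8.56 in cry1. Of 19 circadian clock genes 15 were lower and 0 higher (13 with TMM-type scaling), including PRR9 (-2.53), LNK2 (-2.56) and RVE4 (-1.92). Of 10 dark and sugar starvation genes 8 were lower under both scalings, with DIN1 at -2.80. The camera calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.277, 0.348 and 0.64). Of 18 antenna genes 12 were lower and 0 higher, but 4 with TMM-type scaling, with LHCB1.1 at 38.8 ± 5.74 TPM in WT and 13.2 ± 2.07 in cry1. The antenna call was lost with an estimated correlation (adjusted p = 0.64). Carbon fixation had 3 lower of 10, with RBCS1A at 1100 ± 81.4 and 367.5 ± 45 TPM, and this list did not pass camera (adjusted p = 0.183).

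Of 74 measured genes of the plastid genome 62 were higher and 0 lower in cry1 dark, and in blue light 57 were higher and 1 lower. Camera passed in both, and lost the call with an estimated correlation (adjusted p = 0.137 in the dark and 0.229 in blue light). The plastid genome held 0.21% to 1.03% of the TPM in the WT dark libraries and 1.69% to 1.74% in cry1 dark, and 0.47% to 1.27% in WT blue and 1.60% to 2.64% in cry1 blue. Of 54 mitochondrial genes 12 were higher and 2 lower in the dark (15 and 0 with TMM-type scaling), and 24 higher in blue light, with camera calls lost with an estimated correlation (adjusted p = 0.137 and 0.146). The 4 nuclear rRNA loci held 1.15% to 5.35% of the TPM in WT dark and 4.96% to 12.4% in cry1 dark, and 4.56% to 8.43% in WT blue and 7.95% to 13.0% in cry1 blue. For such a share in 3 against 3 libraries, an exact two-sided permutation test cannot give a p below 0.1. In the light responses, the plastid genome had 2 higher and 1 lower in WT (0 and 0 adjusted over the list alone) and 3 lower in cry1 (2). The mitochondrial genome had 8 lower in WT as deposited, but 3 with TMM-type scaling and 1 adjusted over the list alone, and 1 higher and 1 lower in cry1 (1 and 0 adjusted over the list alone).

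**Figure D4:**
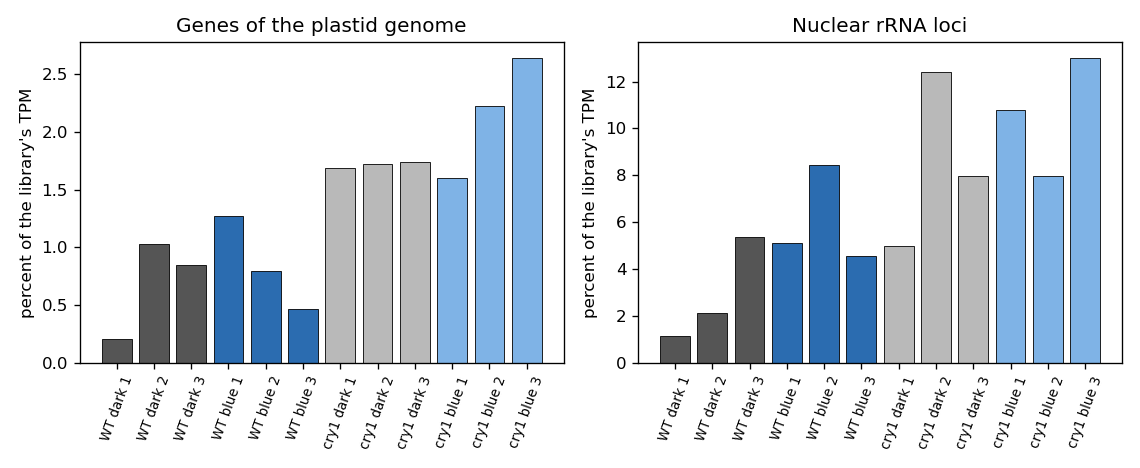
Share of each library's TPM, in percent, held by genes of the plastid genome (left) and by the nuclear rRNA loci (right), as 1 bar per library coloured by group. All 6 cry1 libraries lie above all 6 WT libraries for the plastid genome, whereas the rRNA shares of the genotypes overlap.

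Of other lists in the dark, touch wound and early stress had 4 lower of 19 as deposited, but 2 higher and 2 lower with TMM-type scaling, and the third cry1 dark library stood apart as given above. Without it 13 touch genes were lower, and without WT dark replicate 1 or 2 or cry1 dark replicate 1 or 2, 2 were. Chlorophyll biosynthesis had 1 higher and 5 lower of 20 as deposited (3 and 1 with TMM-type scaling), and medians of -0.32 and -0.04. Cell wall loosening had 2 higher and 3 lower of 16 (5 and 1), and medians of -0.03 and 0.26. Photoreceptors had 6 lower of 14 as deposited and 3 with TMM-type scaling, light signalling 7 of 26 and 5, PIF and related bHLH 7 of 16 and 6, brassinosteroid 5 of 11 and 5, and gibberellin 3 of 16 and 1. The photoreceptor list includes CRY1 itself. Over all 20314 tested genes, 4767 were lower as deposited and 2748 with TMM-type scaling. Reactive oxygen scavenging had 5 lower of 8 as deposited and 1 with TMM-type scaling, with CAT2, a catalase, at 257 ± 3.03 TPM in WT and 56.3 ± 7.74 in cry1. Photoprotection had 5 lower and 1 higher of 12 (3 and 2 with TMM-type scaling), abscisic acid and cold 4 and 1 of 10 (1 and 0), auxin response 5 and 1 of 30 (4 and 2), and root markers 2 lower and 3 higher of 10, with EXPA18 at 1.93. Flavonoid biosynthesis had 1 higher and 1 lower of 16 (3 and 0 with TMM-type scaling), passed camera as higher (adjusted p = 0.0309) and lost the call with an estimated correlation (adjusted p = 0.64). The other lists of this paragraph did not pass camera in the dark. Their adjusted p ran from 0.0522 for photoreceptors and 0.0588 for brassinosteroid to 0.921 for chlorophyll biosynthesis. Of 10 housekeeping genes 1 was higher and 1 lower (1 and 0 with TMM-type scaling). Adjusted over the list alone, the lower counts were 13 for the antenna, 7 for photoreceptors, 9 for PIF and related bHLH, 6 for brassinosteroid, 6 for reactive oxygen scavenging, 2 for touch wound and early stress and 3 for housekeeping, and 63 plastid genes were higher. Seed storage and oil body RNAs were not called in any contrast, and their mean log2 value was 2.76 and 2.64 in the first cry1 dark and the second cry1 blue library, against 0.49 to 1.46 in the other 10.

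The median of all genes in the dark was -0.29 as deposited, and TMM-type scaling shifted it by 0.25. That scaling gave 2315 higher and 2748 lower genes, so that 18.5% of calls were higher as deposited and 45.7% with it. Without WT dark replicate 1, WT dark replicate 2 or cry1 dark replicate 2, 699, 618 or 661 genes were higher and 2342, 2525 or 2188 were lower. Across genes, the genotype difference in the dark correlated with that in blue light at Pearson r = 0.504 and Spearman rho = 0.472, with no libraries in common.

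The light response differed between genotypes for 1863 genes, with 1390 above 0 (a higher response in cry1) and 473 below. Of them, 1377 were also called in the WT light response. For 1039 of these the WT level fell with light and the difference was above 0, and for 275 the WT level rose and the difference was below 0. For 54 the WT level rose and the difference was above 0, and for 9 it fell and the difference was below 0. The WT response is subtracted in the interaction, so noise in the WT libraries favours opposite signs. SAUR19 fell in WT and stood at 26.4 ± 6.4 and 14.4 ± 5.84 TPM in cry1 dark and cry1 blue (interaction 2.46, adjusted p = 0.00342). EXPA8 (2.52), CPD (1.67), GA3OX1 (2.46) and PIF4 (2.16) also had positive interactions. GA3OX1, a gibberellin biosynthesis gene, went from 11.8 ± 0.196 to 3.43 ± 1.09 TPM in WT and from 2.51 ± 0.83 to 5.51 ± 1.56 in cry1. The rise of ELIP2 was smaller in cry1 (-1.71). MYB90 rose in WT (2.04) and stood at 1.63 ± 0.365 and 1.38 ± 0.87 TPM in cry1 dark and cry1 blue (interaction -2.24). HY5 had an interaction of -1.23 (adjusted p = 0.0175), a call lost without cry1 blue replicate 3 (adjusted p = 0.0517).

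Of 30 auxin response genes 12 were above 0 (6 with TMM-type scaling), of 18 antenna genes 7 (3), of 10 root markers 7 (5), of 11 brassinosteroid genes 4 (4), of 16 gibberellin genes 5 and 1 below 0 (3 and 1), and of 10 carbon fixation genes 3 (2). Adjusted over the list alone, above 0 were 13 auxin response, 12 antenna, 9 root marker, 8 brassinosteroid, 9 gibberellin and 3 carbon fixation genes, and below 0 were 13 touch wound and early stress and 3 flavonoid biosynthesis genes. RBCS1A, at 1.94, and LHCA1, at 1.46, were lower in cry1 dark than in WT dark and stood at 1517 ± 207 and 587 ± 45.2 TPM in cry1 blue against 1205 ± 307 and 578 ± 137 in WT blue. Of 19 touch wound and early stress genes 6 were below 0 (8 with TMM-type scaling), with CML37 at -3.68, a call lost without WT blue replicate 2 or cry1 blue replicate 3. Leaving out WT blue replicate 2 or cry1 blue replicate 3 left 0 touch genes below 0. Without WT dark replicate 1 or 3 there was 1, without cry1 blue replicate 1 there were 2, and without WT dark replicate 2 or WT blue replicate 3 there were 3. These 7 lists and flavonoid biosynthesis (1 below 0 of 16, but 5 with TMM-type scaling and 4 with quantile normalization) passed camera. All 8 lost the call with an estimated correlation (adjusted p = 0.477, 0.58, 0.0661, 0.58, 0.58, 0.728, 0.467 and 0.467 in this order). Of the lists that did not pass camera, PIF and related bHLH had 5 above 0 and 1 below of 16 (8 and 3 adjusted over the list alone), cell wall loosening 5 and 1 of 16 (7 and 1), chlorophyll biosynthesis 4 and 0 of 20 (5 and 0), photoreceptors 1 and 0 of 14 (4 and 1) and photoprotection 1 and 1 of 12 (3 and 3), with 2 or fewer over all genes for the others. With TMM-type scaling, 2 cell wall loosening and 1 chlorophyll biosynthesis genes were above 0, and 2 PIF and related bHLH genes and 1 photoreceptor below. The plastid genome, with 2 of 74 below 0, passed camera downward although its median was 0.14, and lost the call with an estimated correlation (adjusted p = 0.737).

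With TMM-type scaling 1220 genes were above 0 and 888 below, so that 74.6% of calls were above 0 as deposited and 57.9% with it. The counts of this contrast changed when single libraries were left out. Whether particular libraries or the smaller number of libraries did this was not tested. Without WT blue replicate 1 or cry1 dark replicate 1, 2068 or 1801 genes were above 0. Without WT dark replicate 1, 2 or 3, WT blue replicate 2 or 3, cry1 dark replicate 2, or cry1 blue replicate 2 or 3, 667, 763, 926, 685, 879, 855, 858 or 563 genes were above 0. Without WT dark replicate 1, 2 or 3, WT blue replicate 1, 2 or 3, or cry1 blue replicate 3, 218, 189, 296, 751, 193, 249 or 130 were below.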

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

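The tests of explanations and the splits in this part were chosen after the results were seen, and the interaction test before. What is listed here is a light response that differed between WT and cry1 by the interaction test of limma (Benjamini-Hochberg adjusted p under 0.05). It differed for 1390 genes with a higher and 473 with a lower response in cry1. Of 100 splits drawn from the 200 that exchange genotype labels within each light condition, 2 called as many genes, the real one included. The real split called 1863 genes and the highest other 1998, which exchanged 2 of the 3 libraries of each genotype in the dark. Whether chance is excluded cannot be read from these splits, because exchanging genotype labels puts the genotype difference into the spread within groups.

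The largest positive interaction log2 fold changes were 5.18 for AT4G22520, 4.93 for AT4G15390, 4.88 for AT2G15880, 4.88 for AT5G44566, 4.31 for AT5G46890, 4.26 for AIR1, 4.203 for AT4G12545 and 4.06 for MLP328. AT2G15880 was listed at 0 in WT blue, AT4G22520 at 0 in cry1 dark, and AT5G44566 at 0 in WT blue and cry1 dark, so their values depend on the pseudocount. The largest negative were -8.97 for AT2G04955, -8.96 for AT1G06553, -6.30 for U1.10, -5.67 for AT3G21305, -5.55 for AT1G53625, -5.39 for AT3G02790, -4.96 for DIR5 and -4.54 for AT4G37290. AT2G04955 and AT1G06553 are annotated as snoRNAs and U1.10 as an snRNA. AT2G04955 was listed at 0 in WT dark, AT1G06553 in WT dark and cry1 blue, U1.10 and AT3G21305 in cry1 blue, and AT3G02790 in every group but cry1 dark, so their values depend on the pseudocount too. The calls of AT5G44566 and U1.10 were lost when single libraries were left out, such as WT blue replicate 2. The medians of lists past camera were 1.33 for root markers, 1.05 for the antenna, 0.81 for brassinosteroid, 0.77 for gibberellin, 0.76 for auxin response, 0.70 for carbon fixation, 0.14 for the plastid genome, -0.67 for flavonoid biosynthesis and -1.25 for touch wound and early stress, where the median of all genes was 0.26. Camera put the plastid genome below other genes, opposite in sign to its median (adjusted p = 0.0309), and lost that call with an estimated correlation (adjusted p = 0.737). The other lists past camera lost their calls with an estimated correlation too, as given above.

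Heat shock RNAs were lower in cry1 both in the dark and in blue light. A difference in scaling between libraries is argued against: with TMM-type scaling the median in the dark was -3.12 (bootstrap interval over genes -3.96 to -2.57). This interval treats the genes as independent (estimated correlation 0.608) and does not measure the spread between libraries. With that scaling 11 of the 12 genes were called lower. Within 1 group, the mean log2 value of the list ranged over up to 1.46 between libraries, less than the mean genotype difference of -3.29. Handling or the day of harvest of the cry1 seedlings cannot be told apart from the genotype, because the labels give neither. An effect of the genotype in the dark stays open too.

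RNAs of the plastid genome were higher in cry1. Antenna RNA gave no sign of more green tissue in the cry1 libraries of the dark. With TMM-type scaling 0 of 18 nuclear antenna genes were higher and 4 lower, with a median of -0.50 (bootstrap interval over genes -0.82 to -0.23). That interval measures the spread between genes, not between libraries. Camera with an estimated correlation gave adjusted p = 0.64, and the chlorophyll biosynthesis median was -0.04 with TMM-type scaling (3 higher, 1 lower). More green tissue is therefore not excluded. RNA without poly(A) tails might have been carried over together with rRNA. Within groups, the log2 shares of plastid RNA and nuclear rRNA loci correlated at Pearson r = 0.53 (permutation p = 0.39 over all 1296 arrangements within groups) and Spearman rho = 0.37 (permutation p = 0.37), with r = 0.39 without the 2 libraries farthest from the median. This cannot be told apart from an effect of the genotype with 3 libraries per group.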

How the results depend on the processing

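Of 488 values of named genes, 423 were called, and 0 of these changed sign under any of the 23 alternatives that gave a value for them, though 76 calls were lost when some 1 library was left out. Of the 65 values not called, 3 changed sign. The naming rule picked genes by large changes or small adjusted p in these same libraries, which favours stable signs. The added log2 fold change of at least 1 used the same fit and could change no sign. The signs are therefore little test of these genes. Between 382 and 488 of the values could be computed under an alternative, and 13 alternatives gave all. The cause of a change was not tested unless given. TMM-type scaling gave 3561 higher and 3384 lower genes for the WT light response, 3322 higher for cry1 against WT in blue light, 2315 higher and 2748 lower in the dark, and 888 below 0 for the interaction. Quantile normalization gave 3163 higher (WT light), 1824 lower (cry1 light), 3641 higher (blue), 2748 higher and 2590 lower (dark) and 894 below 0 (interaction). A log2 fold change of at least 1 left, by construction, 1072 and 2173 (WT light, higher and lower), 1175 and 643 (cry1 light), 1115 and 1564 (blue) and 453 and 1847 (dark). No filter gave 305 below 0 for the interaction. The fit on 19527 nuclear protein-coding genes gave 2085 higher and 5301 lower (WT light) and 2175 and 1311 (cry1 light). It gave 3115 and 2643 in blue, 1386 and 3984 in the dark, and 1955 above 0 and 674 below for the interaction. With each library left out, counts ranged from 1392 to 2089 higher and 3025 to 5737 lower (WT light), 1372 to 2009 and 632 to 1742 (cry1 light), 1231 to 2365 and 1928 to 3312 (blue), 618 to 1137 and 2188 to 5331 (dark), and 563 to 2068 and 130 to 751 (interaction). With an estimated correlation 0 of 14 lists kept their camera call in the WT light response, 4 of 13 in cry1 light, 1 of 12 in blue, 0 of 7 in the dark and 0 of 9 for the interaction. Fry differed from camera in both directions. In the WT light response it called PIF and related bHLH and gibberellin (adjusted p = 0.000998 and 0.00135), but not touch wound and early stress (0.584). In the dark both called heat shock, circadian clock and the plastid genome (fry adjusted p = 0.000439, 0.000439 and 0.00133). There fry alone called further lists, among them housekeeping, gibberellin and auxin response (adjusted p = 0.0146, 0.0146 and 0.0311). It did not call flavonoid biosynthesis (0.565). Fry does not compare a list with the other genes. A shift of all genes, such as the median of -0.29 in the dark, therefore enters its calls. With each library left out, the correlation of the light responses ranged from 0.427 to 0.549 (Pearson r) and from 0.278 to 0.42 (Spearman rho). Count-based tests and scalings, and reads recovered from the values, were not run because TPM keeps no counts. Without read depth, the precision of low values is unknown.

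No pairing of libraries by replicate number was evident: of 18 same-numbered pairs 3 had deviations correlated above 0.1 (range -0.368 to 0.312), and 5 of 12 libraries were closest to one of their own number. With so few libraries this check cannot exclude a pairing, and the labels give none. With the replicate number as a block, 1765 and 4302 genes were higher and lower in the WT light response, 1692 and 895 in cry1 light, 1942 and 2579 in blue, 876 and 4008 in the dark, and 936 and 271 for the interaction.

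Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. In each, 1 split called as many genes, the real one, with 7120, 3031, 5119 and 5849 calls for the WT light response, the cry1 light response, blue and dark, and the highest other split called 5, 2, 2 and 2. Every other split mixes the groups compared, which puts their difference into the spread within groups. The low counts of the other splits therefore decide nothing.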

Other observations

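The tests in this part were chosen after the values were seen. A list of 49 genes known to be induced by low oxygen was compiled from general knowledge, not from a source used here, after several of them had been seen among the largest falls. Of the 49, 35 were lower and 1 higher in WT blue against dark, and 32 were lower in cry1 (camera p = 0.154 and 0.0575 with an estimated correlation). The third cry1 dark library stood apart, with a mean log2 value of these genes of 6.18 against 5.17 and 4.67 in the other two, and 29 were lower in cry1 blue without it. Between genotypes, 22 of the 49 were lower in cry1 dark than in WT dark (13 with TMM-type scaling), and 15 were lower and 2 higher in blue light. The count in the dark was 38 without cry1 dark replicate 3, 8 without cry1 dark replicate 2, and 11 and 10 without WT dark replicates 1 and 2. In blue light the counts ranged from 12 to 20 lower and from 0 to 3 higher with each library left out. None was higher there without WT blue replicate 2 or 3. With an estimated correlation camera gave p = 0.351 in the dark and 0.379 in blue light. Of the 41 that the naming rule had not picked, 27 were lower and 1 higher in WT and 25 lower in cry1, with median log2 fold changes of -1.58 and -1.51 (-1.29 and -1.48 with TMM-type scaling). Camera gave p = 1.31e-08 and 1.95e-17 for these 41, and p = 0.205 and 0.0729 with an estimated correlation. AT4G33070, SUS4 and HB1 are named after their values were seen. LBD41, a transcription factor, went from 245 ± 61.2 to 8.69 ± 6.84 TPM in WT and from 174 ± 108 to 4.71 ± 1.45 in cry1 (SD, n = 3). AT4G33070, a pyruvate decarboxylase, went from 642 ± 260 to 31.3 ± 13.2 and from 333 ± 231 to 13.4 ± 1.55, and SUS4, a sucrose synthase, from 115 ± 52.3 to 2.70 ± 1.52 and from 29.0 ± 33.5 to 1.64 ± 0.52. HB1, a phytoglobin, stood at 1562 ± 390 TPM in WT dark and 592 ± 297 in WT blue. The interaction called 2 of the 49 above 0 and 1 below. With each library left out the counts ranged from 1 to 9 above 0 and from 0 to 2 below, with 9 above 0 without cry1 dark replicate 3, 4 without WT dark replicate 3 and 1 without WT dark replicate 1 or 2 or WT blue replicate 2.

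Besides CRY1, 5 genes had at least 5 TPM in every WT library and under 10% of their lowest WT value in every cry1 library, out of 12520 genes with that WT level: DHAR2, its neighbour AT1G75280, ARGAH1, HSP21 and AT5G62200, while no gene met the mirrored rule in WT. ARGAH1 (19.7 TPM in WT dark and 0.39 in cry1 dark) lies 5 places from CRY1 in the gene order of TAIR10.1, and HSP21 belongs to the heat shock list, of which 12 of 12 genes were lower in cry1 dark, so its low value may go with that list. A candidate explanation is that stretches of the mutant's genome are lost or altered: 1 pair of the 6 genes stood within 3 places of each other, a number reached in 1 of 1000 random sets. The first wording of this test counted any number within the random range against the explanation, and it was changed after the result was seen to leave such a number undecided, so the test cannot settle the matter. Control by blue light through CRY1 was not decided by the WT light response of the 5 genes, with a median absolute log2 fold change of 0.14 (bootstrap interval 0.07 to 1.24), and the low values in cry1 dark, which the rule required, came from libraries given no blue light, where an effect of CRY1 without light was not tested.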
